A study of Mus musculus with 6 samples.

How the data were processed

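RNA from whole kidney was labelled with Cy3 and hybridised to Illumina mouse BeadChips, 1 array per mouse, per the labels. The 3 saline and 3 cisplatin mice were grouped by sample title, and each column of the value table was given to its sample by the sample identifier in the column header. The values deposited by the authors are log2 signals. Their quantiles are nearly equal on all 6 arrays (medians between 6.920 and 6.922), as quantile normalization leaves them. R 2.9.1 is named in the submitters' processing notes. The background correction and the reason for the blank rows are not given in the sources used here. The scale and the lack of centring were read from the values, which are single-channel levels and not ratios.

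A second deposited table lists the same 45281 probe identifiers with 6 columns of values whose names match no sample label. No reported value or test uses those 6 columns. They were looked at while the files were first examined, before the tests of identifiers were chosen, and set side by side with the value table. That look prompted the tests of identifiers. It gave no match between the rows of the 2 tables and left in doubt whether both come from the same arrays. No reported test addresses that doubt. No value from the look is reported, since the columns have no sample labels. Apart from that look, only its identifier column, which is of unit other and holds no measurement, was read, for the order of its rows. As a result the planned start from signals with detection p-values was replaced by the log2 values as deposited, the fallback written before the data were examined. Background correction, detection filters and counts of detected probes were not run.

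Probe identifiers were paired with genes through the platform annotation supplied with the data, and symbols were updated through the Entrez gene number where the GRCm38.p6 RefSeq gene table held it. Of the 22523 rows with values, 17698 had 1 gene symbol, 12 had several and 4813 had none. The symbol came from the RefSeq table for 17633 rows and stayed that of the platform for 65. The 17698 rows carry 10346 distinct symbols.

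Whether values belong to the identifiers beside them was then tested. In each gene with at least 2 rows holding values, the first 2 rows in identifier order were paired, and Spearman's rho across genes was set against 10000 random pairings. For each fixed gene list with at least 3 rows, the median percentile of the rows' mean level was set against 10000 random row sets of the same size. The values were also moved by up to 50 rows in either direction along the second table's order, and the pairs were correlated again. These tests were chosen after the values had been seen, and only the shift was specified before its own result was known. Because the pairs and the shifts gave no relation between identifier and value, the rule for named genes fixed beforehand, which took the 12 largest rises and 12 largest falls, 12 genes by name and up to 4 members per list, was not applied. Gene list tests were not run for the same reason, and the reported counts use every row, with no choice of a probe per gene.

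Rows were compared with limma 3.58.1 in R 4.3.3, by lmFit with group as the only term and eBayes with default settings, followed by Benjamini-Hochberg adjustment over the 22523 rows. A row counted as changed at an adjusted p under 0.05, and as changed at least 2-fold at an absolute log2 difference of at least 1 in addition. The residual degrees of freedom were 4 per row and the prior added 15.2. The median standard error of a log2 difference was 0.072.

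Alternatives fixed before the data were examined were median scaling, cyclic loess, array weights, an intensity trend with a robust prior, the replicate number as a block, and leaving out each of the 6 arrays in turn. Added after seeing the data were a restriction to rows above the median level, a restriction to rows with a mean of at least 8, and 1 row per listed gene name, the row with the highest mean over the 6 arrays, used only to thin the rows. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

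The scripts were tested on simulated data. For the comparison of cisplatin with saline over 22523 rows, 200 rows were changed by known amounts, 50 at each of 4 sizes. All rows changed by 1, 2 or 3 on the log2 scale were recovered (100%). Of those changed by 0.5, 82.0% were recovered, and 11 unchanged rows were called. The simulated noise was normal and had no floor, and a far smaller share of rows was changed than passed the test in the real data. The recovered shares therefore need not hold for the real rows. For the test of identifiers, simulated levels were the sum of a part shared by the rows of one gene and a row's own part. The 2 parts had equal variance and the levels had no floor. These levels gave a rho of 0.481, and the same levels after shuffling gave 0.015. The first value follows from that setting and does not say what right identifiers would give on these arrays.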

Results

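Kidney RNA from 6 male C57BL/6 mice, an inbred laboratory strain, was measured on Illumina BeadChips, arrays on which each probe reports the abundance of one transcript sequence. The mice were 9 weeks old. A group of 3 mice had received 1 intraperitoneal injection of cisplatin, a platinum drug that cross-links DNA and injures the renal tubule, at 15 mg/kg, and a group of 3 had received saline. Kidneys were taken 3 days after the injection. The value table lists 45281 probe identifiers, of which 22523 hold a log2 value on all 6 arrays and 22758 are blank on all 6. The median log2 value was 6.92 on each of the 6 arrays, and the values ran from 6.05 to 15.8 over all of them. The number of arrays limits the precision. The limma p-values rest on the spread between the 3 mice per group, moderated by the spread over all rows. The permutation p-values concern rows and measure no spread between mice.

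The gene names that the identifiers carry were set against the values before any gene was compared. Among 4405 genes with at least 2 rows holding values, the mean log2 level of the first row had a Spearman rho of -0.016 with that of the second, across genes. Random pairings gave -0.030 to 0.029, and the permutation p was 0.273 (two-sided, 0.369 after Benjamini-Hochberg adjustment over the 2 relations computed). The log2 difference between cisplatin and saline had a rho of 0.014 between the same pairs of rows, with a permutation p of 0.369 (adjusted p = 0.369). Genes are not independent replicates, so these p-values describe the pairing of rows only. Of 474 pairs in which both rows passed the limma test described next, 237 moved the same way in both, or 50.0% (95% exact binomial interval 45.4% to 54.6%).

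Over the 32 gene lists fixed beforehand that had at least 3 rows with values, the median level of the list's rows was set against random sets of rows of the same size. No list differed after Benjamini-Hochberg adjustment (smallest adjusted permutation p = 0.077), and 4 of the 32 had an unadjusted p under 0.05. These 4 were androgen-dependent kidney genes, whose 11 rows had a median at percentile 83.7 of all rows (permutation p = 0.0071), adipocyte genes at 7.24 with 5 rows (permutation p = 0.0072), cell death effectors at 69.5 with 46 rows (permutation p = 0.0052) and reference genes, widely expressed genes, at 76.0 with 15 rows (permutation p = 0.024). The adjusted p was 0.077 for each of the first 3 and 0.194 for the reference genes. The 52 rows of respiratory chain subunits had a median at percentile 49.2 (random sets 37.0 to 62.9). Single genes were mixed. The row of Gapdh, a glycolytic enzyme, had a mean log2 value of 10.6, and the highest rows of B2m, the light chain of class I histocompatibility molecules, and Eef1a1, a translation elongation factor, had 13.0 and 12.6. The highest rows of Actb, cytoplasmic beta-actin, and Aqp1, a water channel of the proximal tubule, had 8.75 and 8.27. Both rows of Rplp0, a ribosomal protein, had 6.60 and 6.67, both rows of Fth1, the ferritin heavy chain, 6.49 and 6.69, and the single rows of Gpx3, a plasma glutathione peroxidase, and Alb, serum albumin, 6.90 and 6.59. Gapdh, B2m, Actb and Rplp0 also belong to the list of reference genes, so they add no separate evidence to it. All these single genes were chosen after values had been seen and decide nothing about the identifiers.

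Rows with values also followed the first letter of the gene name. Of rows whose gene symbol opens with a digit or a letter from A to G, 90.9% held values, against 27.7% of those opening with H to Z. In the row order of a second table with the same 45281 identifiers, the rows with values were positions 1 to 22523 without a gap. Because of the uncorrelated pairs and this block of rows, the identifiers were not used to name any row, and no cisplatin response is given for a gene or a gene list. Of the 12 kidney and stress genes fixed beforehand for naming, among them Havcr1, Lcn2 and Umod, 2 had a row with values, namely Cdkn1a and Egf.

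**Figure D1:**
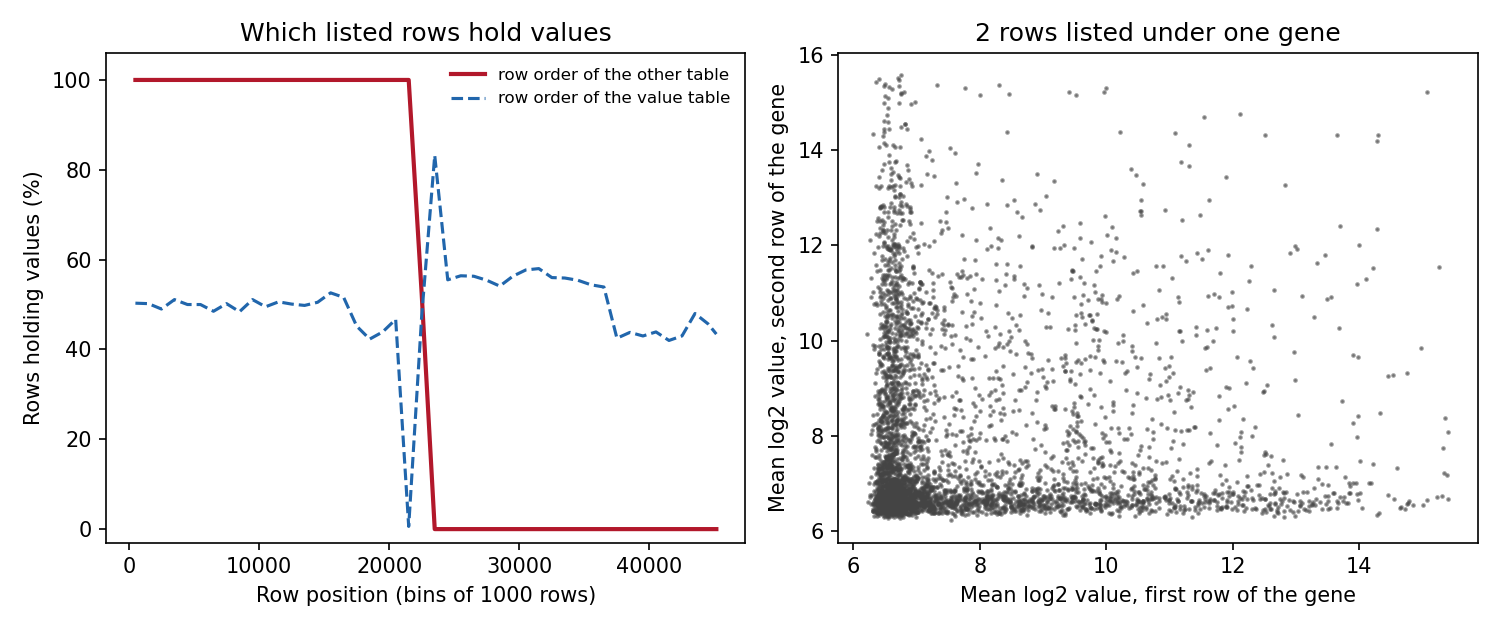
Left, the percentage of listed rows that hold values in bins of 1000 rows, against row position in the value table's own order (dashed) and in the order of the second table (solid), where it is 100% up to position 22000 and 0% from position 23001. Right, mean log2 value over the 6 arrays of the first and second row of each of 4405 genes, 1 point per gene, with a Spearman rho of -0.016.

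The comparison of cisplatin with saline asks how the kidney's RNA differs 3 days after the drug. It was made over the 22523 rows, each taken as 1 unnamed array feature. By limma's moderated test with Benjamini-Hochberg adjustment, 7210 rows (32.0%) differed at an adjusted p under 0.05, of which 3239 were higher and 3971 lower after cisplatin. The median size of a change among these rows was 0.49 on the log2 scale, or 1.40-fold. At least a 2-fold change was found in 1147 of them, 620 higher and 527 lower. Changes of at least 8-fold were mostly rises, with 60 rows higher and 14 lower. The median log2 difference over all rows was -0.0012.

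The highest rise took a row from 8.86 ± 0.38 (SD, n = 3) in saline to 15.5 ± 0.040 (SD, n = 3) after cisplatin, a log2 difference of 6.64 with a limma adjusted p of 1.47e-19. Its cisplatin level lay close to the top of the value range, so a ceiling is not excluded for its size and rank. The next went from 7.01 ± 0.19 to 13.0 ± 0.16 (SD, n = 3 each), with a limma adjusted p of 2.18e-20. Its saline level lay close to the array median, and signal over background was not measured, so its size and rank are those of the values as given. The row with the largest fall went from 11.99 ± 0.0090 to 7.58 ± 0.075 (SD, n = 3 each), a log2 difference of -4.40 with a limma adjusted p of 2.18e-20. The next fell by 4.02 on the log2 scale, from 11.7 ± 0.081 to 7.66 ± 0.058 (SD, n = 3 each), with a limma adjusted p of 1.03e-19.

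With the rows divided by mean level over all 6 arrays into 4 bins of equal size, 1.62% of the lowest bin, which reached 6.62, passed the test, and 6.25% of the next. The share was 48.3% in the third bin and 71.9% in the highest, which began at 8.63. A strong change itself raises or lowers the mean that sets the bin, and the values have a floor near 6, so these shares do not show how often rows dim in one group changed.

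The 2 groups were apart on the arrays as a whole. Pearson's r across rows was 0.998 for the 3 pairs of saline arrays and 0.996 to 0.998 for the 3 pairs of cisplatin arrays. It was 0.962 to 0.966 for the 9 pairs of one saline and one cisplatin array. The first principal component held 90.8% of the variance, with the saline arrays between -38.5 and -36.3 and the cisplatin arrays between 36.7 and 38.3. In 9091 rows, or 40.4%, the 3 values after cisplatin all lay above or all lay below the 3 saline values, where chance gives 10%. The median SD of a row between mice, over all rows and so including the many near the floor, was 0.070 in saline and 0.081 after cisplatin. Which transcript each row measures was not settled, nor whether these values and the second table come from the same arrays. The counts therefore describe the values in the labelled columns and cannot be read as numbers of genes. Reading them, or the size of the contrast, as the effect of cisplatin in these kidneys depends on that unsettled point.

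**Figure D2:**
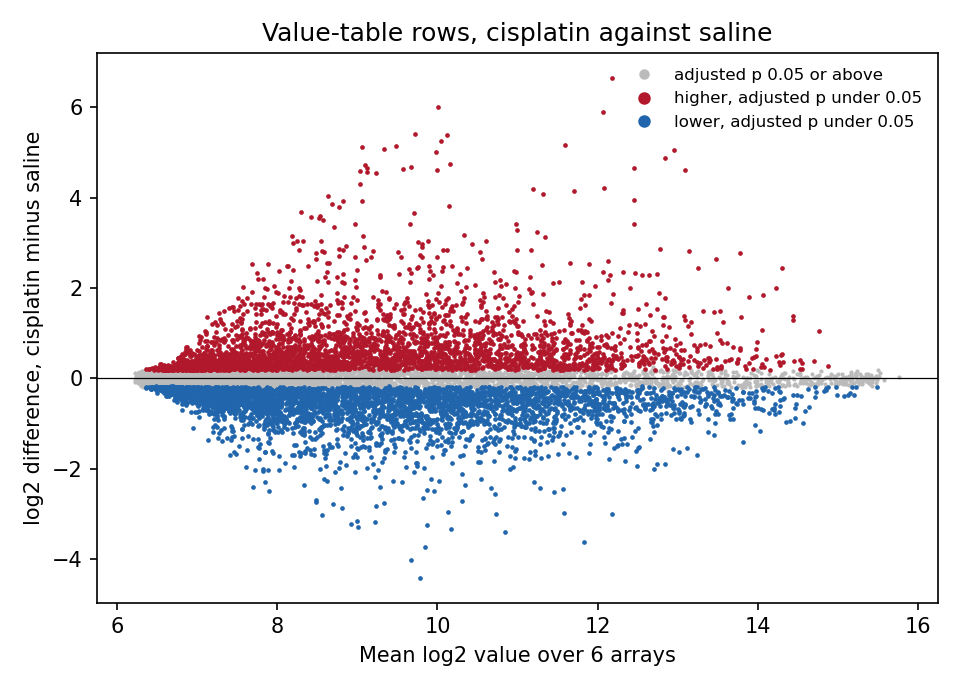
Log2 difference between cisplatin and saline (cisplatin minus saline) against the mean log2 value over the 6 arrays, 1 point per row, 22523 rows. Coloured points are the 3239 higher and 3971 lower rows with a limma adjusted p under 0.05.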

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

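Over 14 alternatives, 11 fixed beforehand and 3 chosen after seeing the data, 52 of 56 counts stayed within 1.5 times the reported ones. The 4 others all come from keeping 1 row per listed gene name, which leaves 10346 rows to test. It gave 4317 changed rows, 1980 higher, 2337 lower and 709 changed at least 2-fold. Fewer rows were tested, and 41.7% of them changed. That share is not like for like, since the row with the highest mean was kept and higher levels held more changed rows. Some counts had little room to move. The arrays already shared nearly the same median, and all changes of at least 2-fold lay above the median level. Changed rows were 32.0% of all rows, 62.2% of those above the median level and 73.7% of those with a mean of at least 8. Leaving out 1 array at a time gave 6533 to 7240 changed rows, 2930 to 3249 higher, 3603 to 3991 lower and 1132 to 1177 changed at least 2-fold. Cyclic loess moved the share of rises among changed rows from 44.9% to 48.9%. Called rows present in each alternative kept their sign in all 14. With the trend and robust prior, the replicate block and the 3 restrictions of rows, the log2 difference is the same by construction. No sign could change there, and median scaling hardly moved the values. The highest and next highest rise and the largest and next largest fall stayed past the threshold in every one of the 53 values computed. With the replicate block there were 7361 changed rows, 3339 higher, 4022 lower and 1148 changed at least 2-fold. Deviations from the group means correlated at -0.032, 0.116 and 0.075 for arrays of one number, so the numbers are not taken to pair the mice, and not every array correlated best with its own number. Normexp with an offset, no background correction, filters on detection p, the mean over a gene's probes and the gene list tests were not run, since they need signals, detection p-values or named rows. The authors' values with no filter are the reported setting. Signal over background was not measured here.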

Other observations

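The tests of identifiers against values, other than the shift by a few rows, were chosen only after their results had been seen. The tests of the difference between groups were written before their own results were computed, but after an approximate number of changed rows had been seen. No explanation in terms of genes or pathways was tested, because rows carry no usable gene names.

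Values and probe identifiers did not go together. If the identifiers were right and probes of one gene merely disagreed, rows of one gene should still share part of their level. The rho of -0.016 over 4405 genes argues against that. How large a rho right identifiers would give on these arrays, where many rows lie near the floor, was not measured. Levels of 3 gene lists lay where right identifiers would put them in male kidney (androgen-dependent and reference genes high, adipocyte genes low), but none passed adjustment over 32 lists. These 3 were picked from the lists with an unadjusted permutation p under 0.05. Rows of proximal tubule transporters and of respiratory chain subunits had medians at percentiles 54.5 and 49.2, inside the range of random sets. The transporters had only 13 rows, from 7 of 31 genes, and random sets of that size ran from 25.05 to 75.03. That range is too wide for the transporters to tell right from wrong identifiers. The respiratory chain subunits had 52 rows, from 35 of 96 genes (random sets 37.0 to 62.9). Blanks left for low signal would not follow the alphabet, yet the share of rows with values differed by 63.1 percentage points between early and late gene symbols. Moving the values by up to 50 rows along the second table's order gave a highest rho of 0.032, so a small shift in that order does not restore the pairing. Shifts in another order were not tried. An explanation left open is that a shorter block of 22523 value rows may have been set beside the first 22523 identifiers of a list in another order. It would leave no row with values outside that block, and 0 rows lie outside it. Explanations other than those named here were not tested. The order the values were in, and whether they were measured on the arrays of the second table, stay open.

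The 2 groups of arrays differed in 7210 rows. The 10 splits of 6 arrays into 3 and 3 are too few for a share under 0.05. Of these, 1, the real one, gave as many rows, and the highest of the other splits gave 0. Every other split mixes the groups, so the group difference enters its residual spread and lowers its count. The other splits therefore do not show what arrays without a group difference would give. No single array made the difference, as the lowest count without one array was 6533. Cisplatin replicate 3 stood apart from the other cisplatin arrays on the second principal component (14.5 against -6.45 and -8.35). Leaving out that array gave 7240 changed rows. Another scaling gave at least 7206 rows, but the arrays already share one distribution, so this could not show whether a shift of whole arrays was present before normalization. The labels name cisplatin as the difference between the groups, and no batch that separates them is recorded. What stays open is whether the values in these columns were measured on these kidneys.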
